A study of Mus musculus with 12 samples.

How the data were processed

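The 12 samples were epidermal cells from the back skin of female Gata6 reporter mice in telogen, separated by flow cytometry into 4 populations of 3 samples, which the labels call biological replicates. Per the labels, RNA was isolated with a column kit for small amounts, amplified and converted to biotin-labelled cDNA, and hybridized to Affymetrix mouse exon arrays. The deposited values are intensities of 235932 exon probe sets, which the authors made with robust multi-array average (RMA) processing in Affymetrix Power Tools on the mouse genome build mm9, per the submitters' processing notes; versions were not stated. Their scale was not stated and was taken to be linear from the values, with array medians of 3.97 to 4.57 and maxima of 2172 to 2953, although RMA usually gives log2 values; every log2 level and fold here rests on this reading. RMA sets background and scale across arrays, so a shift shared by most genes of an array is reduced before the values were read here. Array number limits the precision of all values.

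Gene symbols came with the probe sets, and a reference gene table of assembly GRCm38.p6 served only to bring them up to date: 15377 symbols were current, 2489 were updated and 42 kept. Of the probe sets, 221205 had 1 symbol, 1684 several and 13043 no listed gene; only those with 1 symbol were used. Intensities were taken as log2 of the value plus 1, and a gene's level was the median of its probe sets (median 10 per gene; 959 genes had 1). The added 1 makes fold changes of dim genes smaller. This gave 17853 genes. The 95th percentile of 1144 olfactory and vomeronasal receptor genes, 2.46 on the log2 scale, was taken as the level of silent genes, and 8745 genes lay under it in all populations. No coordinates are given, because the reference table is of another build.

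A linear model with 1 mean per population was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with variances moderated across genes (prior degrees of freedom 2.12, residual 8). The 6 pairs of populations were compared, 4 of them as main comparisons. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes, and folds are 2 to the power of the log2 change. Where the lower mean lay under the level of silent genes the fold was taken against that level and is a lower bound; log2 changes of called genes are given in the report where both means lay over it. Overlaps of called lists were set beside lists of the same lengths, ranked by limma's statistic, from 100 simulations of the 12 arrays without any effect, beside the number called in simulations. The overlap with remaining basal cells was also counted with 1 of their arrays for one population and the other 2 for the other, against independent lists within 10 bins of gene level. These references and the bound on folds were chosen after the values were seen. Levels are given as mean ± SD and changes with the model's SE. An exact permutation test of 3 against 3 samples cannot go below 0.1 and was not used for single genes.

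Gene lists, 27 with 576 different genes, were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and most of the alternative settings. They cover bulge stem cells, interfollicular basal cells, upper follicle and junctional zone, sebaceous gland, spinous and granular differentiation, hemidesmosome and basement membrane, tight junction and desmosome, cell cycle, the Wnt, BMP and TGF-beta, and Notch pathways, antimicrobial and epithelial defence, cholesterol synthesis, NRF2 and xenobiotic response, glycolysis and hypoxia, interferon response, dissociation stress, inner root sheath and hair shaft, companion layer and inner bulge, Merkel cell, Langerhans cell and macrophage, T cell, melanocyte, dermal fibroblast, endothelial cell, skeletal muscle and adipocyte, and erythrocyte. Of these genes, 40 were not analysed here. The 26 lists with at least 5 measured genes were tested with camera of limma, with a preset correlation between genes of 0.01 and, as an alternative, an estimated one; p-values were adjusted over the lists of a comparison.

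The named genes are the sort genes Gata6, Itga6 and Cd34; the 8 largest higher and 8 largest lower called genes of each main comparison whose replicates did not overlap, passing over predicted gene models; the 3 members with the smallest adjusted p of each called list and at most 1 of other lists; the 12 genes of each signature with the largest smallest fold; and the markers Krt5, Krt14, Krt1, Krt10, Krt79, Lrig1, Plet1, Lgr5, Krt15 and Ly6a. Some are also given in comparisons for which the rule did not pick them. Ccn2, Nfatc1, Itgb4, Col17a1, Lgr6, Sostdc1, Col1a2, Col3a1, Dcn and Cd207 were chosen after their values were seen.

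The procedure was tested on simulated data with planted changes in 17853 genes. For the comparison of Gata6+Itga6+ with CD34+ cells it recovered 14%, 44%, 92% and 100% of 50 genes each planted at log2 changes of 0.5, 1, 2 and 3, and for that with remaining basal cells 18%, 50%, 92% and 96%; 7 genes without a planted change were called in each. A planted list was called and 0 others. The simulated genes varied independently, whereas the upper follicle list had an estimated correlation of 0.325 in the data. The simulation therefore says nothing about false list calls among correlated genes. Alternatives were other gene summaries (mean, brightest probe set, brighter probe sets), normalizations (quantile, centring, array brightness as a covariate), variance models, array weights, blocks, a filter on dim genes, no added 1, fits of only the populations compared, and each array left out. Array brightness is the upper quartile of an array's intensities. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the values and drew the figures.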

Results

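Gene expression was measured on 12 exon arrays in 4 populations of epidermal cells sorted from the back skin of female mice in telogen, the resting phase of the hair cycle, with 3 biological replicates per population. The mice carried a Gata6 reporter, so that red fluorescence marked cells in which this zinc-finger transcription factor was active. Integrin alpha 6 (Itga6) sits on basal keratinocytes, which touch the basement membrane, and CD34 marks stem cells of the hair follicle bulge in mouse skin. Cells with the Gata6 reporter were divided into Gata6+Itga6+ and Gata6+Itga6− populations. Those without it were divided into Itga6+ cells with CD34 (CD34+ cells) and Itga6+ cells that lacked CD34, here called remaining basal cells. The comparisons ask which genes set basal Gata6+ cells apart from the other basal populations, and which genes differ within Gata6+ cells between those with and those without Itga6. The number of arrays limits the precision of every value, and the 12 arrays were not equally bright: their upper quartile of intensity ran from 12.1 to 17.6.

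Replicates of a population correlated at r = 0.935 to 0.957 across genes, and arrays of different populations at 0.828 to 0.941; genes are not independent replicates. The first principal component held 30.95% of the variance and placed Gata6+Itga6− arrays at 40.9 to 43.8 and CD34+ arrays at −54.2 to −43.8. The second held 19.3% and placed the remaining basal arrays lowest, at −45.1 to −35.1. The third held 15.6% and parted replicates. Remaining basal replicate 3 was at −24.4 against 27.1 and 20.5 for replicates 1 and 2, and Gata6+Itga6− replicate 2 at −6.87 against 21.9 and 21.4. CD34+ replicates 1 to 3 were at 26.5, 11.6 and −9.58. The Gata6+Itga6+ arrays lay at −36.3 to −20.5, a range that also held remaining basal replicate 3.

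**Figure D1:**
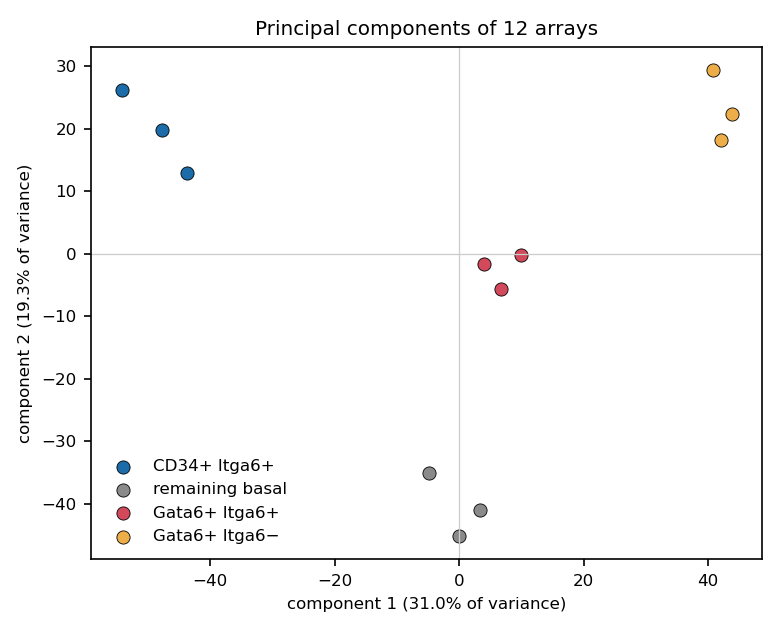
Principal components of the 12 arrays, with 1 point per array, coloured by population; the axes are component scores in arbitrary units, with the percent of variance in each axis label. Arrays of a population lie together on the first and second components, which hold 30.95% and 19.3% of the variance.

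The genes used for the sort followed the gates. Cd34 had a log2 level of 7.95 ± 0.033 in CD34+ cells (SD, n = 3) and of 1.78 ± 0.20 in Gata6+Itga6+, 1.96 ± 0.19 in Gata6+Itga6− and 1.66 ± 0.16 in remaining basal cells. Gata6 stood at 5.84 ± 0.046 in Gata6+Itga6− and 4.39 ± 0.34 in Gata6+Itga6+ cells, against 2.84 ± 0.29 in CD34+ and 2.73 ± 0.34 in remaining basal cells. These Gata6 values are medians of 16 probe sets, several of which hardly moved between populations; the probe set with the widest gap gave 9.56, 7.95, 2.16 and 2.71 in the same order. Itga6 was lower in Gata6+Itga6− than in Gata6+Itga6+ cells (log2 change −1.27, SE 0.26, limma adjusted p = 0.0268) but still at 6.02 ± 0.31, and it was not called without Gata6+Itga6+ replicate 1, 2 or 3 (0.0549, 0.0892 and 0.0933) or Gata6+Itga6− replicate 1 or 3 (0.102 and 0.0947). Since the cells were sorted on these genes, their differences check the labels and are not findings.

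**Figure D2:**
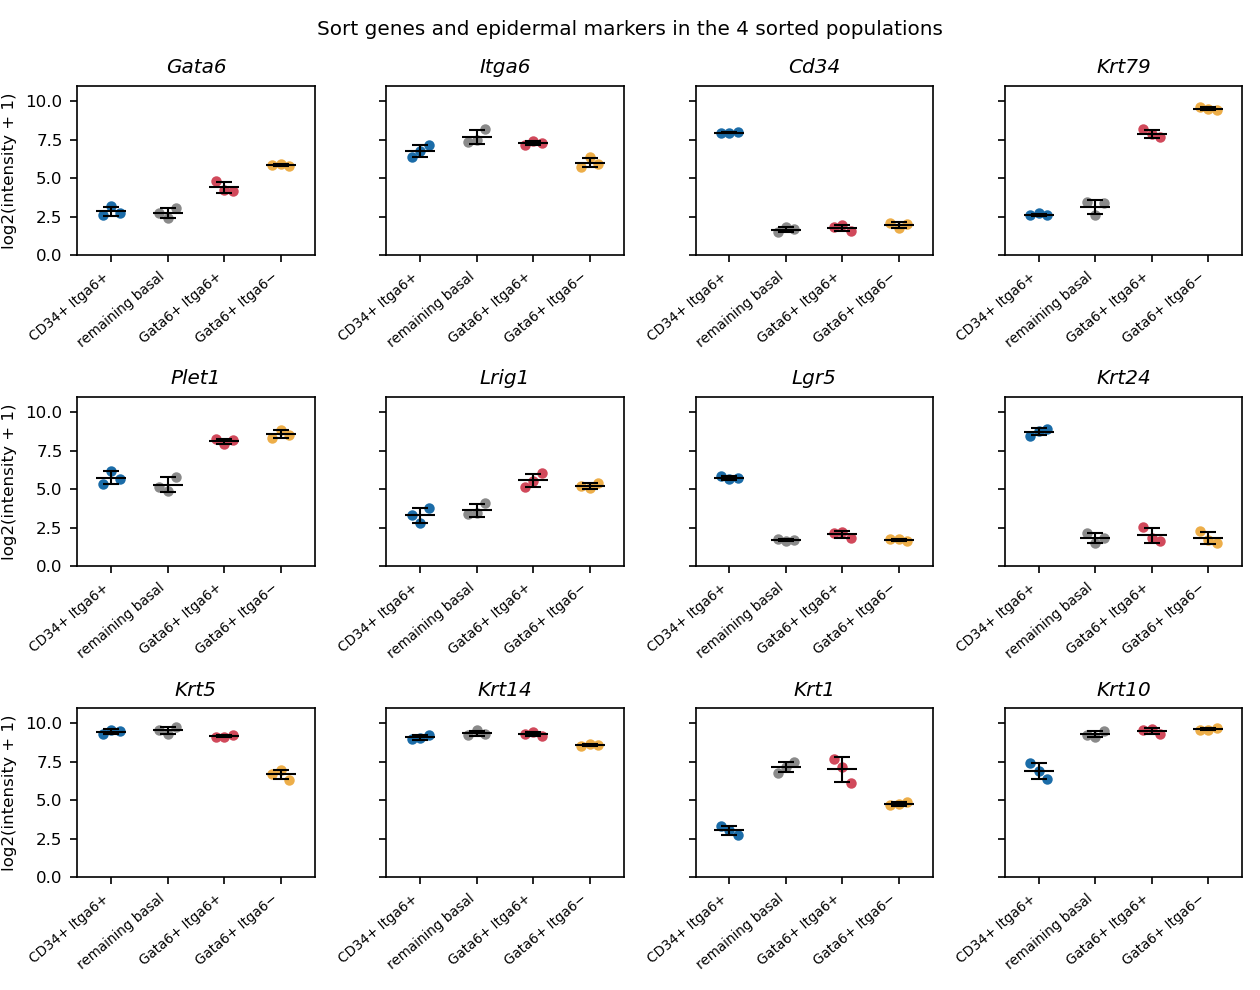
Log2 gene levels on each array for the sort genes and epidermal markers, by population; each point is 1 replicate, and the lines show the mean with its SD (n = 3). Cd34 is at 7.95 in CD34+ cells and under 2 elsewhere, and Krt79 is at 7.91 and 9.52 in the Gata6+ populations.

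Compared with CD34+ bulge cells, Gata6+Itga6+ cells had higher levels of 7 of 12 upper hair follicle genes and lower levels of 14 of 25 bulge genes. A fold is written as at least where the lower mean lay under 2.46, the level of silent genes, and is then taken against that level. Defb6, a beta-defensin, was at least 45.2-fold higher (log2 7.96 ± 0.47 against 1.90 ± 0.16, n = 3), Aadac, an arylacetamide deacetylase, at least 23.97-fold higher and Krt79, a keratin of the upper follicle, 38.7-fold higher (log2 7.91 ± 0.26 against 2.63 ± 0.065). The protease inhibitor Cst6 was at least 26.5-fold and the cyclin-dependent kinase inhibitor Cdkn1a 21.1-fold higher. Ly6d was 26.3-fold higher (log2 7.98 ± 0.38 against 3.26 ± 1.1), a log2 change of 4.72 that was 5.35 without CD34+ replicate 2. In the other direction, the bulge keratin Krt24 was at least 76.9-fold lower (log2 2.01 ± 0.49 against 8.73 ± 0.23), S100a4 62.4-fold, the matrix protein Sparc 57.3-fold, the interleukin-31 receptor Il31ra at least 27.5-fold and the secreted Wnt antagonist Sfrp1 38.8-fold lower. Limma adjusted p-values of these genes ran from 1.1e-07 for Aadac to 0.000168 for Ly6d; with only its brightest probe set, Krt24 was not called.

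Of 25 measured bulge stem cell genes, 14 were lower in Gata6+Itga6+ cells and 11 did not pass the test (18 lower adjusted over the list alone; limma camera adjusted p = 1.9e-26). Lgr5, a receptor of follicle stem cells, was at least 9.72-fold lower and Angptl7 at least 24.5-fold. The upper follicle and junctional zone list was higher, with 7 of 12 genes called and none lower (9 adjusted over the list alone; adjusted p = 3.7e-15). Besides Defb6, Krt79 and Cst6 these included Lrig1 (log2 change 2.26, SE 0.30) and Plet1 (2.40, SE 0.27), markers of the junctional zone. Cell cycle genes were higher, 15 of 29 (26 adjusted over the list alone; adjusted p = 9.3e-23), among them Top2a, a topoisomerase of dividing cells, at least 6.58-fold and Mki67, a proliferation marker, at least 5.11-fold. Of 37 genes of spinous and granular differentiation, 10 were higher (10 adjusted over the list alone; adjusted p = 9.6e-09). They included the desmosomal cadherins Dsc1 (at least 9.51-fold) and Dsg1a (log2 change 3.55, SE 0.29), the suprabasal keratins Krt1 (3.97, SE 0.34) and Krt10 (2.59, SE 0.22), and the transcription factor Grhl3 (2.13, SE 0.14). The basal keratins Krt5 and Krt14, and the keratin Krt15 of the bulge list, were not called. Their log2 levels were 9.17, 9.30 and 9.87 in Gata6+Itga6+ cells and 9.47, 9.10 and 9.94 in CD34+ cells. Krt15 was also at 9.78 in remaining basal and 9.63 in Gata6+Itga6− cells.

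The dermal fibroblast list, included to watch for other cells in the sort, was lower in Gata6+Itga6+ than in CD34+ cells, with 4 of 16 genes called (5 adjusted over the list alone; adjusted p = 3.7e-05). The called genes were Sparc, Col6a1, Col6a2 and Col1a2, while Col3a1 and Dcn, abundant in fibroblasts, stood at 1.82 and 1.63 in CD34+ cells, below the level of 2.46 used here for silent genes. Each of the 5 lists named so far was also called with an estimated correlation (adjusted p = 0.00768 for bulge, 0.0253 for upper follicle, 0.0192 for cell cycle, 0.0303 for differentiation and 0.0192 for fibroblast). Genes of the hemidesmosome and basement membrane were lower, 2 of 17 (5 adjusted over the list alone; adjusted p = 0.000172, but adjusted p = 0.0855 with an estimated correlation). These were the integrin Itga2 (−2.16, SE 0.20) and the collagen Col7a1 (−1.31, SE 0.18). Tight junction and desmosome genes were higher, 4 of 24 (9 higher and 3 lower adjusted over the list alone; adjusted p = 0.00688, but adjusted p = 0.270 with an estimated correlation). The plakophilin Pkp1 was up by 2.54 (SE 0.23). Cholesterol synthesis genes were higher, 2 of 17 (2 adjusted over the list alone; adjusted p = 0.0122, but adjusted p = 0.141 with an estimated correlation; 0.0763 without Gata6+Itga6+ replicate 1), with the synthase Hmgcs1 5.65-fold higher.

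In all, 819 of 17853 genes differed between Gata6+Itga6+ and CD34+ cells at an adjusted p under 0.05, 429 higher and 390 lower, and 622 of them by at least 2-fold. The larger share turned to lower without CD34+ replicate 1 (251 higher, 356 lower) or CD34+ replicate 2 (304 and 367), after another quantile normalization (445 and 456) and with array brightness as a covariate (487 and 492). In each of the 819 the replicates of the populations did not overlap; chance separates 3 from 3 in 10% of genes and 19.5% of all genes were separated. The mean of a gene's probe sets in place of their median called 1300 genes, and the brightest probe set alone 503.

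Against the remaining basal cells, Gata6+Itga6+ cells differed in fewer genes, and the upper follicle genes were again among the highest. Defb6 was at least 45.2-fold higher (log2 7.96 ± 0.47 against 2.16 ± 0.47, n = 3), Aadac at least 23.97-fold, Cst6 at least 26.5-fold and Krt79 27.6-fold. The membrane glycoprotein Cd200 was at least 17.2-fold higher (log2 6.56 ± 0.64 against 2.33 ± 0.41), the claudin Cldn8 at least 11.7-fold, the ectonucleotidase Enpp1 at least 8.42-fold and Abi3bp 13.7-fold. Lower in Gata6+Itga6+ cells were Il1r2, the decoy receptor of interleukin 1, by 15.1-fold (log2 2.65 ± 0.85 against 6.56 ± 0.54), the receptor chain Il12rb2 by 9.63-fold, Antxr1 by 8.09-fold, Ndufa4l2 by 6.39-fold and the growth factor Bmp4 by at least 4.84-fold. Limma adjusted p-values ran from 4.3e-07 for Aadac to 0.00768 for Antxr1.

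Of 12 upper follicle and junctional zone genes, 8 were higher and none lower (9 higher adjusted over the list alone; adjusted p = 2.0e-16, but adjusted p = 0.0735 with an estimated correlation). They included Plet1 (log2 change 2.85, SE 0.27) and Lrig1 (1.94, SE 0.30), whose call was lost without remaining basal replicate 1 or 2 (adjusted p = 0.0541 and 0.0613). Bulge stem cell genes were higher, 5 of 25 (8 higher and 2 lower adjusted over the list alone; adjusted p = 0.000515, but adjusted p = 0.255 with an estimated correlation). They were Cd200, the activin antagonist Fst (3.73, SE 0.19), the transcription factors Lhx2 (2.59, SE 0.18) and Nfatc1 (1.65), and Ccn2 (1.77). Most of these genes were not particular to Gata6+Itga6+ cells. In Gata6+Itga6− and remaining basal cells, Lhx2 stood at 5.67 and 2.57, Fst at 6.49 and 3.92, and Nfatc1 at 4.27 and 2.62. Cd200 was likewise higher in Gata6+Itga6− cells, but Ccn2 hardly so (3.06 and 3.02). Lhx2 reached 5.16 in Gata6+Itga6+ and 8.41 in CD34+ cells. Lgr5 and Cd34 were not called in Gata6+Itga6+ against remaining basal cells, at 2.07 against 1.70 and 1.78 against 1.66. Differentiation genes were higher, 5 of 37 (8 higher and 1 lower adjusted over the list alone; adjusted p = 0.00552, but adjusted p = 0.255 with an estimated correlation). Dsc1 was at least 9.51-fold higher and Grhl3 up by a log2 change of 1.11 (SE 0.14), while Krt1 and Krt10 were not called (−0.15, SE 0.34, and 0.20, SE 0.22).

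Cell cycle genes were higher with 2 of 29 called (2 adjusted over the list alone; adjusted p = 0.000415, but adjusted p = 0.257 with an estimated correlation). Top2a was up by 1.40 (SE 0.27, adjusted p = 0.0372). Top2a was not called in 10 of the 12 fits that left out 1 array. The NRF2 and xenobiotic response list was higher, 3 of 26 (5 adjusted over the list alone; adjusted p = 0.00957, but adjusted p = 0.255 with an estimated correlation). Its called genes were the aldehyde dehydrogenases Aldh3a1 (2.38, SE 0.33) and Aldh1a1 (at least 2.78-fold) and the cytochrome P450 Cyp1b1 (at least 4.78-fold, adjusted p = 0.0497). Leaving out single arrays ended the call of Aldh1a1 (adjusted p up to 0.0933, without Gata6+Itga6+ replicate 3) and of Cyp1b1 (up to 0.1535, without the same array). Tight junction and desmosome genes were higher, 2 of 24 (3 adjusted over the list alone; adjusted p = 0.0105, but adjusted p = 0.305 with an estimated correlation), led by Cldn8.

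Lists lower in Gata6+Itga6+ than in remaining basal cells held few called members. Dissociation stress genes, immediate early genes that tissue digestion can induce, had 0 of 20 called (3 lower adjusted over the list alone; adjusted p = 0.000515, but adjusted p = 0.255 with an estimated correlation). Nr4a1 was at −1.19 (SE 0.26, adjusted p = 0.0666) and Junb at −0.76 (SE 0.22, adjusted p = 0.173). Dermal fibroblast genes had 1 of 16 lower, Sparc by a log2 change of −2.38 (2 adjusted over the list alone; adjusted p = 0.0240, but adjusted p = 0.193 with an estimated correlation). Antimicrobial and epithelial defence genes had 1 of 35 lower (1 adjusted over the list alone) and inner root sheath and hair shaft genes 0 of 23 (0 adjusted over the list alone), each with an adjusted p of 0.0339, but adjusted p = 0.193 with an estimated correlation. The fibroblast, root sheath, defence and tight junction calls ended after another quantile normalization (0.0819, 0.177, 0.308 and 0.408), and the last 3 without the dimmest 33.3% of genes (0.0584, 0.134 and 0.0811). None of these calls of the defence, root sheath, fibroblast and tight junction lists held when array brightness entered the fit as a covariate (adjusted p from 0.115 to 0.792), and the xenobiotic list then stood at 0.0533. Single arrays also ended calls: that of differentiation without Gata6+Itga6+ replicate 1 (0.0523), that of fibroblasts without Gata6+Itga6+ replicate 2 or 3 (0.0528 and 0.0807). That of the root sheath was lost without remaining basal replicate 1 or 2 or Gata6+Itga6+ replicate 2 (0.0704, 0.185 and 0.120), and that of defence without any of these 3 or Gata6+Itga6+ replicate 3 (0.0704, 0.125, 0.1345 and 0.0964).

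The comparison called 242 genes, 191 higher and 51 lower in Gata6+Itga6+ cells, which is 78.9% higher; this share was 56.3% (162 higher, 126 lower) after another quantile normalization and 62.2% (79 higher, 48 lower) with array brightness as a covariate. The count was 127 with that covariate, 110 in a fit of only these populations, 454 with the mean of probe sets, and 137, 131, 146 and 139 without remaining basal replicate 1, remaining basal replicate 2, Gata6+Itga6+ replicate 1 and Gata6+Itga6+ replicate 3. Without remaining basal replicate 3, 304 genes were higher and 39 lower.

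**Figure D3:**
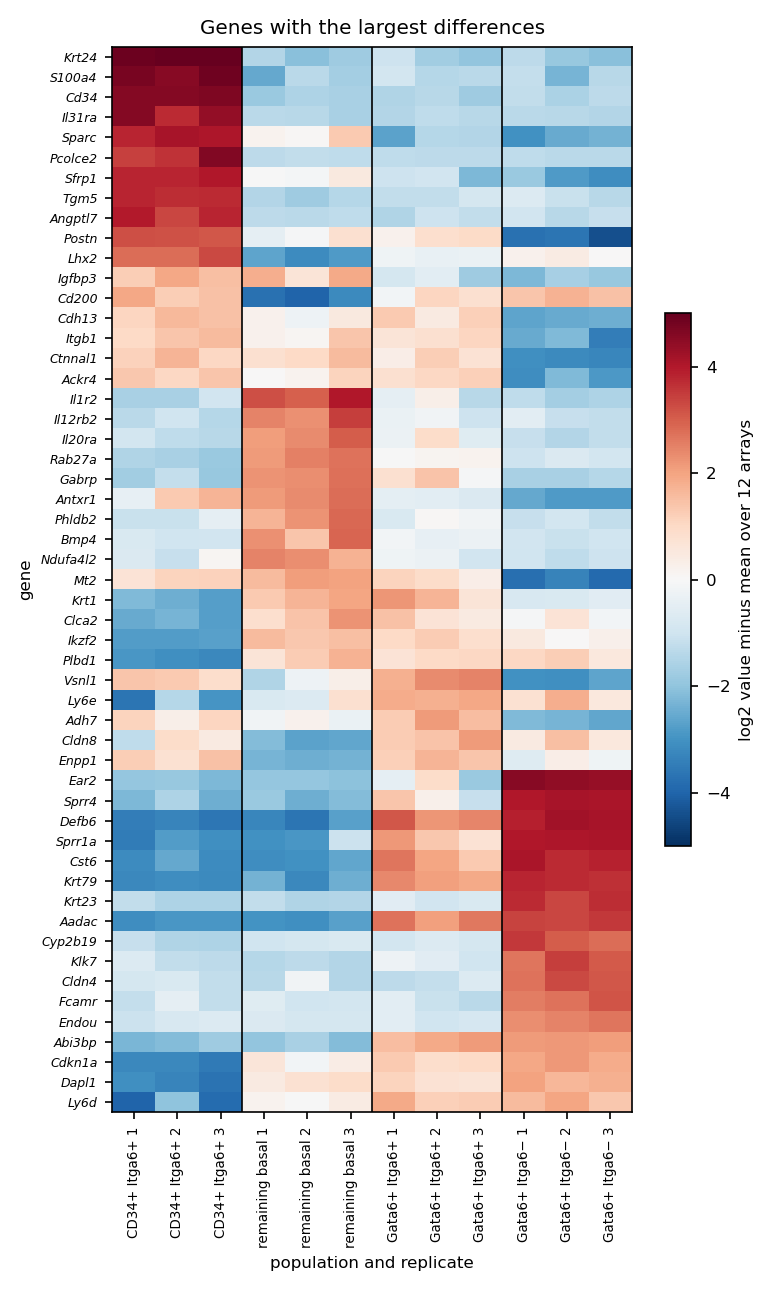
Heat map of the genes with the largest differences named by the fixed rule, 53 genes by 12 arrays; colour is the log2 level relative to the gene's mean over all arrays, limited at 5 in either direction, and columns are grouped by population. Most genes are highest in CD34+ cells (17 genes) or Gata6+Itga6− cells (17 genes).

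A basal Gata6 signature was defined as genes at least 2-fold higher in Gata6+Itga6+ than in both CD34+ and remaining basal cells, each past the threshold. It held 65 genes, including the sort gene Gata6 itself. Both comparisons use the same Gata6+Itga6+ arrays. In 100 simulations without any effect 0 genes met the same definition, since hardly any was called, and lists of top genes forced to these lengths, called or not, shared 45.0 on average (highest 64). The largest were Defb6, Aadac, Cst6, Krt79, Abi3bp, Sprr1a, Alox12e, Dsc1, Crabp2, Acsl4, Gas7 and Ptgr1. Their smaller fold over the other basal populations ran from at least 45.2 for Defb6 to 7.15 for Ptgr1. Among them are a cornified envelope precursor (Sprr1a), an epidermal lipoxygenase (Alox12e), a retinoic acid binding protein (Crabp2), an acyl-CoA ligase (Acsl4) and a prostaglandin reductase (Ptgr1). Of the 65 genes, 49, Gata6 again included, were also at least 2-fold higher in Gata6+Itga6− cells than in both CD34+ and remaining basal cells. Between the Gata6+ populations, 21 of the 65 were higher and 9 lower in Gata6+Itga6− cells and 35 were not called. The comparisons behind the shared signature also share arrays. The basal count was 34 with array brightness as a covariate (33 of them among the 65), 28 in fits of only 2 populations, and 42 or 40 without remaining basal replicate 1 or 2. The shared count was 27 with that covariate and 22 in fits of only 2 populations.

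Within Gata6+ cells, those without Itga6 showed higher genes of spinous and granular differentiation. Their interfollicular basal, hemidesmosome and basement membrane, and cell cycle genes were lower. Because the gate divided these cells on Itga6, which sits on basal keratinocytes, differences in basal genes are not independent of the sort. The ribonuclease gene Ear2, measured by 1 probe set, was 30.1-fold higher (log2 7.81 ± 0.095 against 2.90 ± 1.4, n = 3). Its log2 change of 4.91 was 4.22 without Gata6+Itga6+ replicate 3. Without Gata6+Itga6+ replicate 2 it was 5.61, but the Gata6+Itga6+ mean then lay under the level of silent genes, so this value is not exact. The keratin Krt23 was at least 17.1-fold (6.56 ± 0.20 against 2.22 ± 0.19), the claudin Cldn4 at least 12.9-fold, the keratinocyte cytochrome P450 Cyp2b19 15.6-fold and the skin protease Klk7 12.8-fold higher. Vsnl1, a calcium sensor, was at least 21.05-fold lower (1.74 ± 0.24 against 6.86 ± 0.37), the matrix protein Postn at least 23.1-fold, the metallothionein Mt2 at least 17.2-fold, the alcohol dehydrogenase Adh7 16.5-fold, the catenin-like Ctnnal1 at least 9.79-fold, and the integrin Itgb1, partner of Itga6 and other alpha chains, 11.8-fold lower. Limma adjusted p-values ran from 5.8e-07 for Krt23 to 0.000891 for Itgb1.

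Of 37 differentiation genes, 12 were higher and 1 lower (17 and 1 adjusted over the list alone; adjusted p = 6.7e-13). The cornified envelope protein Ivl rose by 2.86 (SE 0.23), the protease inhibitor Spink5 by 2.18, and the cross-linking enzyme Tgm1 was at least 2.17-fold higher. The lower gene was Krt1 (−2.23, SE 0.34, adjusted p = 0.00725). Its usual partner Krt10 was not called (0.12, SE 0.22; −0.17 after another quantile normalization). Cell cycle genes were lower, 14 of 29 (26 adjusted over the list alone; adjusted p = 1.1e-24), with Top2a at least 6.58-fold and Mcm6, part of the replicative helicase, at least 6.33-fold lower. Hemidesmosome and basement membrane genes were lower, 7 of 17 (12 adjusted over the list alone; adjusted p = 1.1e-13), among them Itgb1, Lamb3 (at least 4.95-fold), Col17a1 (log2 change −1.89, SE 0.28) and Itgb4 (−1.78, SE 0.32). Interfollicular basal genes were lower, 9 of 15 and none higher (9 lower and 1 higher adjusted over the list alone; adjusted p = 3.9e-12), including Mt2, Mt1 (−3.17, SE 0.24), Krt5 (−2.49, SE 0.17) and Krt14 (−0.70, SE 0.12). With an estimated correlation these 4 lists stood at an adjusted p of 0.0113 each.

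Upper follicle genes went both ways, 7 of 12 higher and 2 lower (8 and 2 adjusted over the list alone; adjusted p = 1.1e-06 for higher, but adjusted p = 0.109 with an estimated correlation). Klk10 (3.13, SE 0.36), Cst6 (1.90, SE 0.31) and Krt79 (1.61, SE 0.21) were higher, and Lgr6 and Sostdc1 (−2.06) lower. Tight junction and desmosome genes were higher, 5 of 24, with 1 lower (5 and 1 adjusted over the list alone; adjusted p = 2.4e-06, but adjusted p = 0.0951 with an estimated correlation). Cldn4, Cgn (1.51, SE 0.24) and Cldn23 (at least 1.46-fold) were higher and Dsg2 (−1.65) lower. BMP and TGF-beta genes were lower, 5 of 29 (7 adjusted over the list alone; adjusted p = 0.0272, but adjusted p = 0.322 with an estimated correlation). Tgfbi was at −2.85 (SE 0.29) and the ligand Tgfb2 was at least 2.05-fold lower. Antimicrobial and epithelial defence genes were called higher with 2 of 35 higher and 1 lower (2 and 1 adjusted over the list alone; adjusted p = 0.0237, but adjusted p = 0.0941 with an estimated correlation). They were the peptidoglycan receptor Pglyrp3 (at least 3.22-fold) and Krt16 (at least 1.28-fold) against the alarmin Il33 (at least 4.32-fold lower). Krt16 and Il33 both lost the call without Gata6+Itga6+ replicate 1, 2 or 3 or Gata6+Itga6− replicate 1 or 2 (Krt16 0.114, 0.151, 0.112, 0.171 and 0.144; Il33 0.0569, 0.0709, 0.0901, 0.0641 and 0.0724). Companion layer and inner bulge genes had 1 of 11 higher, Krt16 (1 higher and 1 lower adjusted over the list alone; adjusted p = 0.0284, but adjusted p = 0.162 with an estimated correlation).

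No gene of the immune cell lists was called. The T cell list was higher by camera with 0 of 12 genes called (0 adjusted over the list alone; adjusted p = 0.0135, but adjusted p = 0.199 with an estimated correlation). Cd3g was at 2.48 against 1.61 (adjusted p = 0.216). The Langerhans cell and macrophage list was higher with 0 of 16 called (0 adjusted over the list alone; adjusted p = 0.0231, but adjusted p = 0.107 with an estimated correlation). H2-Aa was at 3.38 against 2.10 (adjusted p = 0.264) and Cd207 at 1.91 against 1.71 (adjusted p = 0.466). These immune, defence and companion layer calls were lost with array brightness as a covariate (adjusted p from 0.124 to 0.522), as was that of the BMP and TGF-beta list (0.110). Another quantile normalization also ended the T cell and Langerhans calls (0.0812 each) and those of the companion layer and defence lists (0.0869 and 0.0990). Leaving out the dimmest 33.3% of genes ended the Langerhans and BMP calls (0.124 each). Each also depended on single arrays. T cell was lost without Gata6+Itga6− replicate 3 (0.1348), and Langerhans without that array or Gata6+Itga6+ replicate 2 or 3 (0.0854, 0.0622 and 0.0920). BMP was lost without Gata6+Itga6+ replicate 1 or Gata6+Itga6− replicate 1 or 2 (0.101, 0.0709 and 0.0516). Companion layer was lost without Gata6+Itga6+ replicate 1 or 2 or Gata6+Itga6− replicate 2 (0.0546, 0.0736 and 0.0652), and defence without Gata6+Itga6+ replicate 2 or 3 or Gata6+Itga6− replicate 1 (0.0571, 0.065 and 0.0709).

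The 567 called genes were 208 higher and 359 lower in Gata6+Itga6− cells, or 36.7% higher; the share was 47.9% (312 higher, 339 lower) after another quantile normalization and 49.5% (183 higher, 187 lower) with array brightness as a covariate, which left 370 genes. The mean of probe sets called 995 genes, and the count was 373, 285, 325 and 304 without Gata6+Itga6+ replicate 2 or 3 and Gata6+Itga6− replicate 1 or 3. Without Gata6+Itga6− replicate 2, 135 genes were higher and 287 lower.

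CD34+ cells against remaining basal cells, both negative for the Gata6 reporter, gave a measure of how far basal populations differ without it. Krt24 was at least 76.9-fold higher in CD34+ cells (log2 8.73 ± 0.23 against 1.80 ± 0.32, n = 3), S100a4 at least 82.0-fold, the transcription factor Lhx2 57.2-fold, Il31ra at least 27.5-fold, the transglutaminase Tgm5 at least 37.9-fold, Cd200 at least 33.4-fold and Pcolce2, an enhancer of collagen processing, at least 18.8-fold. Il1r2 was at least 17.2-fold lower (1.76 ± 0.37 against 6.56 ± 0.54), Plbd1 at least 16.7-fold, the transcription factor Ikzf2 at least 18.4-fold, the vesicle protein Rab27a at least 13.3-fold and Krt1 17.3-fold lower. Limma adjusted p-values ran from 5.8e-08 for Lhx2 to 5.0e-05 for Il1r2.

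Of 25 bulge stem cell genes, 20 were higher and none lower (23 adjusted over the list alone; adjusted p = 1.6e-33, and 0.00338 with an estimated correlation). They included Angptl7 (at least 24.5-fold) and Lgr5 (at least 9.72-fold), whose brightest probe set alone gave a log2 change of −0.20 and no call. Interfollicular basal genes were lower, 5 of 15, with 1 higher (7 and 2 adjusted over the list alone; adjusted p = 0.000749, but adjusted p = 0.141 with an estimated correlation). The surface antigen gene Ly6a was at least 9.53-fold lower and the water channel Aqp3 higher (log2 change 3.51, SE 0.24). Differentiation genes were lower, 8 of 37, with 1 higher (8 and 1 adjusted over the list alone; adjusted p = 0.000411, but adjusted p = 0.141 with an estimated correlation). Dsg1a was at −3.55 (SE 0.29) and Krt10 at −2.40 (SE 0.22). Cell cycle genes were lower, 7 of 29 (17 adjusted over the list alone; adjusted p = 3.9e-15, but adjusted p = 0.0677 with an estimated correlation), with Top2a at least 2.502-fold lower.

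BMP and TGF-beta genes were called higher with 7 of 29 higher and 2 lower (7 and 2 adjusted over the list alone; adjusted p = 0.0145, but adjusted p = 0.329 with an estimated correlation). The BMP antagonist Grem1 was at least 13.1-fold higher and Bmp4 at least 4.84-fold lower. Dissociation stress genes were lower, 7 of 20, with 1 higher (8 and 1 adjusted over the list alone; adjusted p = 0.00111, but adjusted p = 0.270 with an estimated correlation). The phosphatase Dusp1 was at a log2 change of −1.94 (SE 0.32) and the immediate early gene Egr1 at −1.88 (SE 0.33). Dermal fibroblast genes were higher, 4 of 16 (5 adjusted over the list alone; adjusted p = 0.0109, but adjusted p = 0.141 with an estimated correlation). Col6a1 was at least 6.99-fold higher and Sparc up by a log2 change of 3.46 (SE 0.39). Hemidesmosome and basement membrane genes were called higher with 1 of 17 higher and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.00908, but adjusted p = 0.200 with an estimated correlation). Lamb3 was the higher one (0.92, SE 0.21, adjusted p = 0.0355), a call lost, among other arrays, without CD34+ replicate 1 or 3 or remaining basal replicate 1 or 2 (0.108, 0.120, 0.0653 and 0.125). The hemidesmosome and BMP lists were not called with array brightness as a covariate (adjusted p = 0.0867 and 0.0762), and the hemidesmosome list not after another quantile normalization (0.118).

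This comparison called 892 genes, 593 higher and 299 lower in CD34+ cells, or 66.5% higher; the share was 52.8% (612 higher, 548 lower) after another quantile normalization and 50.2% (435 higher, 432 lower) with array brightness as a covariate. A fit of only these populations called 571 genes, and the mean of probe sets 1513.

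**Figure D4:**
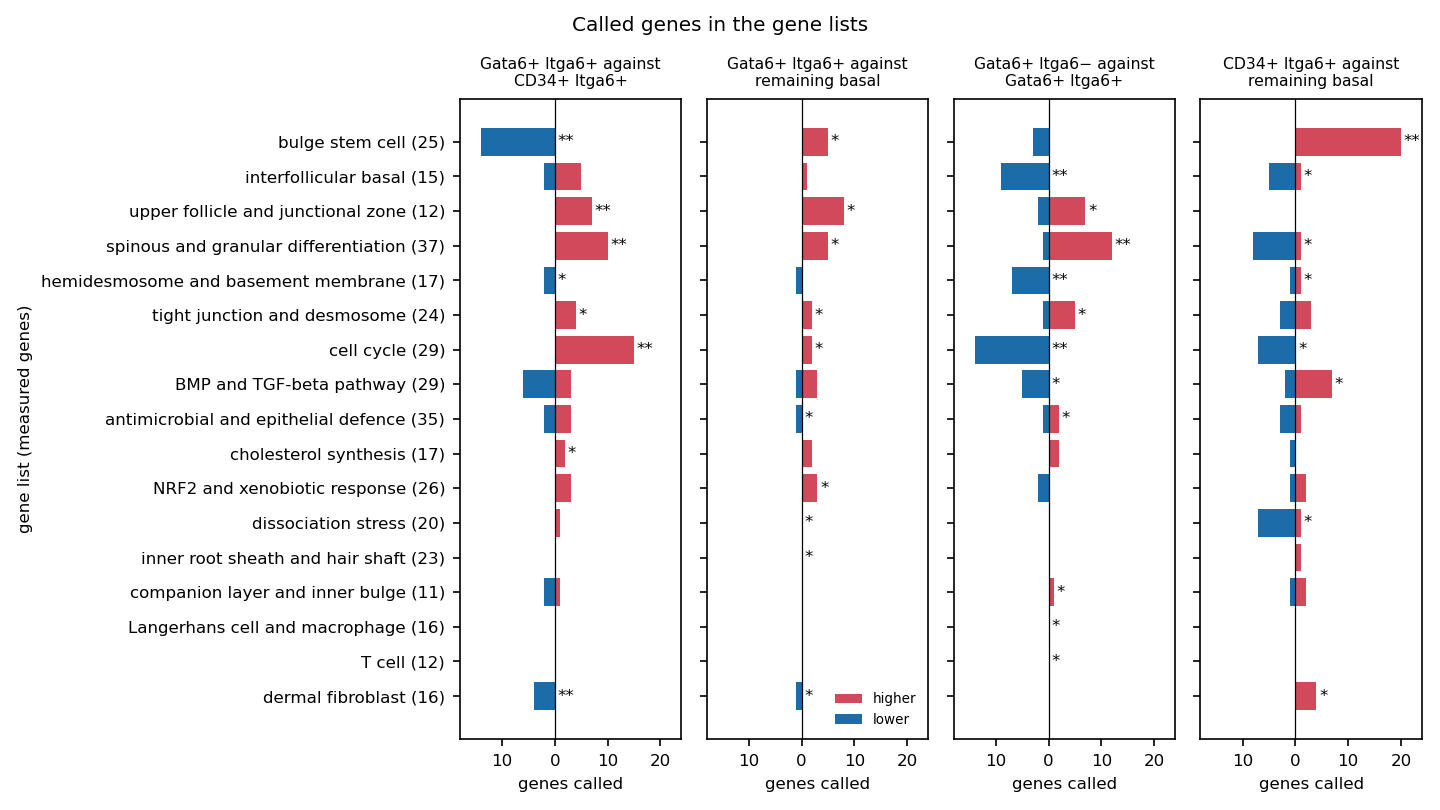
Number of genes higher (right of 0) and lower (left of 0) at an adjusted p under 0.05 in the gene lists called in at least 1 of the 4 main comparisons, with 1 panel per comparison and the number of measured genes in brackets. An asterisk marks a list called by camera with the preset correlation, and 2 asterisks a list also called with an estimated correlation; bulge genes are lower in Gata6+Itga6+ than in CD34+ cells (14 of 25) and cell cycle genes lower in Gata6+Itga6− than in Gata6+Itga6+ cells (14 of 29).

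Lists called in none of the 4 comparisons were those of the sebaceous gland, Wnt pathway, Notch pathway, glycolysis and hypoxia, interferon response, Merkel cell, melanocyte, endothelial cell, and skeletal muscle and adipocyte. Single members still differed: Acsl1 was at least 9.43-fold higher in Gata6+Itga6+ than in CD34+ cells, and the R-spondin receptor gene Lgr4 9.72-fold higher in CD34+ than in remaining basal cells. The Notch ligand Jag1 was 4.82-fold lower in Gata6+Itga6+ than in CD34+ cells, and the transcription factor Mitf 7.56-fold higher in CD34+ than in remaining basal cells. No Merkel cell, endothelial or muscle and adipocyte gene was called in any of the 4 comparisons, and none of the 3 measured erythrocyte genes, too few for a list test, was called. For no called list did the median, the mean and the test differ in sign. They did for some others: against remaining basal cells, the interfollicular basal list in Gata6+Itga6+ cells had a median log2 change of −0.27, a mean of 0.024 and a test direction of lower (adjusted p = 0.156), and the Wnt list a median of −0.025, a mean of 0.18 and a test direction of lower (0.816).

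Gata6+Itga6− cells differed from CD34+ cells in 1421 genes (574 higher and 847 lower, 40.4% higher; 51.4% with array brightness as a covariate, 738 higher and 698 lower) and from remaining basal cells in 913 (529 higher and 384 lower, 57.9% higher). Against CD34+ cells 516 were higher and 564 lower without Gata6+Itga6− replicate 1. Against remaining basal cells the larger share turned to lower without remaining basal replicate 1 (362 higher, 382 lower, 48.7% higher). It was 51.3% higher after another quantile normalization (655 and 622) and 51.6% with the covariate (608 and 570). Without Gata6+Itga6− replicate 1 or 3 there were 459 higher and 253 or 240 lower. The mean of probe sets gave 2159 and 1403.

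Gata6+Itga6+ and CD34+ cells were also set side by side against the remaining basal cells. Higher in both were 73 genes and lower in both 34. In 100 simulations without any effect and with the same shared arrays, 0 genes were called in both in either direction, since hardly any was called at all. Lists of top genes forced to the real lengths, called or not, shared 70.6 on average (highest 91) for higher and 20.2 (highest 27) for lower. With separate remaining basal arrays for each population, the overlap was 6.08 to 10.9 times that of independent lists of genes of like level, over the 6 ways to divide the arrays. In each way 1 population was set against a single remaining basal array, and not all of the overlapping genes were among the 73. Higher in Gata6+Itga6+ and lower in CD34+ cells were 9 genes, and the reverse held for 1 gene. Among the 73 were Cd200, Fst, Enpp1, Lhx2, Lgr4, Aqp3 and Cldn8, all named above. Across genes the log2 changes correlated at 0.430, where the shared remaining basal arrays alone gave 0.502 in simulation; their covariance was 0.104 against a simulated 0.0325, a difference of 0.0712.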

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

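The tests of array brightness as a covariate on the imbalance and on the changes of the 73 genes, of the simulated overlap, of separate remaining basal arrays, of CD34+ cells in the Gata6+ gate and of saturated probe sets were chosen after the result was seen. The tests of the other splits, of the matched library, of the covariance with shared libraries and of the overlap count with brightness were not.

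Probe sets with no listed gene, 13043 in number and not used for any gene value, also differed between populations in limma at an adjusted p under 0.05. Between Gata6+Itga6+ and CD34+ cells 119 were called (48 higher, 71 lower). Against remaining basal cells 89 were called in Gata6+Itga6+ cells (82 higher, 7 lower) and 266 in CD34+ cells (222 higher, 44 lower). Between Gata6+Itga6− and Gata6+Itga6+ cells 46 were called (24 higher, 22 lower).

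The 6 arrays of a comparison can be split in 10 ways, too few for a share under 0.05, and the real split (1 of 10) called the most genes in each. The real and the highest other split called 819 and 0 genes for Gata6+Itga6+ against CD34+ cells, 242 and 6 against remaining basal cells, 567 and 1 for Gata6+Itga6− against Gata6+Itga6+ cells, and 892 and 1 for CD34+ against remaining basal cells. They called 1421 and 0 for Gata6+Itga6− against CD34+ cells and 913 and 1 against remaining basal cells. For gene lists the real and highest other values in the 4 main comparisons were 8 and 7, 10 and 4, 11 and 8, and 8 and 5. Of 100 regroupings of the 12 arrays, 1, the real one, gave a basal signature as large as 65 genes (highest other 56). Likewise only the real grouping gave a shared signature as large as 49 (highest other 0). Other groupings mix populations, which raises the spread within groups, so the real grouping was favoured beforehand. The regroupings therefore speak only against arrays without any population difference and decide nothing about the size of either signature.

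More genes were higher than lower in Gata6+Itga6+ against remaining basal cells (78.9% of those called). Mean array brightness was 16.047 in Gata6+Itga6+ and 13.507 in remaining basal cells, whose replicate 3 alone was as bright (15.961). Of genes differing by at least 2 on the log2 scale, 58.333% were higher against that replicate, and 90.58% and 88.387% against the dimmer replicates 1 and 2, which is consistent with brightness as a source of the imbalance but rests on 1 array. With brightness as a covariate 62.205% of called genes were higher, between the bounds set for and against it. Brightness and a real imbalance cannot be told apart by this covariate test, because it removes what brightness and population share; a biological difference stays open and untested.

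A total of 73 genes were higher in both Gata6+Itga6+ and CD34+ cells than in remaining basal cells. CD34+ cells inside the Gata6+ gate would bring all their transcripts, but the 20 genes with the largest CD34+ fold reached a median of 4.7891% of their CD34+ level in Gata6+Itga6+ cells (Krt24 0.125%, Cd34 0.112%), against a lower quartile of 30.424% for the 73, and 8 of the 20 are among the 73. With different remaining basal arrays subtracted, the covariance of the differences over all genes, not the 73 alone, stayed above 0 in all 6 pairings (lowest 0.01957), which argues against shared arrays as the whole cause of that covariance. With 1 remaining basal array for one population and the other 2 for the other, all 6 ways gave an overlap at least 6.0836 times that of independent lists of genes of like level. In each way 1 comparison rested on a single remaining basal array, which gives no spread of its own. Not all of the overlapping genes were among the 73. This argues against shared arrays as the whole cause of the overlap, but not for each of the 73 genes. A shift common to several remaining basal arrays, such as lower brightness, could give this overlap and the covariance without shared arrays. Neither reference holds such a shift. Simulations without any effect decide nothing about the number: 0 genes were called in both, which was bound to be so, and lists of these lengths filled with genes not called had 70.58 in common on average (highest 91). With brightness as a covariate 37 genes, all among the 73, were higher in both, and brightness cannot be told apart by this count, because simulated lists of those lengths shared 43.9 (highest 54). The bound set for it before, a multiple of the 1.92 of independent lists, ignored the shared arrays. Over all 73 genes the median log2 change with the covariate was 1.5993 in place of 2.02 in Gata6+Itga6+ cells and 2.13 in place of 2.47 in CD34+ cells. Each gene stayed over 2 SE (lowest 0.63). The genes had been selected on the same arrays at a stricter bar, so this was likely beforehand and decides nothing about brightness. In the 36 genes no longer called in both, the median in Gata6+Itga6+ cells fell from 1.58 (SE 0.27) to 1.34 (SE 0.32), a smaller change with a larger error. Most of the 73 genes also had a higher mean in Gata6+Itga6− than in remaining basal cells. For most, the higher level was thus not particular to Gata6+Itga6+ and CD34+ cells. A program shared by the populations, or a fall in remaining basal cells alone, may underlie the 73 genes, as hypotheses found and tested on the same data.

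Krt1 was lower in Gata6+Itga6− than in Gata6+Itga6+ cells (−2.23, its 12 probe sets from −3.39 to −1.59) while Krt10 was not called (0.12). Saturation of bright Krt10 probe sets could hide a fall. The dimmer 5 of 10 changed by a median of −0.11036 (−0.19 to 0.26). Their Gata6+Itga6+ levels ran from 7.34 to 9.45, so some were hardly dimmer than the rest, the brightest of which was at 11.0. The dimmest, at 7.34 and 8.12, changed by −0.11 and −0.19. These values argue only against saturation hiding a fall as large as that of Krt1. Krt1 stayed called after another quantile normalization (−1.93), centring (−2.17) and the brightness covariate (−2.27), while Krt10, not called in any of these, changed sign with the first and the last (−0.17, 0.17 and −0.01). No biological explanation for Krt1 falling without Krt10 was tested.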

How the results depend on the processing

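The log2 values without an added 1, the brighter probe sets, the brightness covariate, and the quantile and centred values for gene lists were chosen after seeing the data; all other alternatives were planned. For counts of genes, signatures and lists, 120 alternatives that left out no array stayed within 1.5 times the reported value and 28 moved. The mean of probe sets called 1300, 454, 995, 1513, 2159 and 1403 genes for comparisons 1 to 6. These are, in order, Gata6+Itga6+ against CD34+ and against remaining basal, Gata6+Itga6− against Gata6+Itga6+, CD34+ against remaining basal, and Gata6+Itga6− against CD34+ and against remaining basal cells. The brightest probe set called 503 in comparison 1. The brighter probe sets called 434, 977, 1484 and 1516 in comparisons 2, 3, 4 and 6, with signatures of 100 (53 of the 65 shared) and 76. The brightness covariate called 127 in comparison 2 and 370 in comparison 3, with signatures of 34 and 27 and 6 lists in each of these comparisons. Fits of only 2 populations called 110 in comparison 2 and 571 in comparison 4, with signatures of 28 and 22, having fewer arrays. An estimated correlation called 5, 0, 4 and 1 lists in the main comparisons, and quantile values 7 in comparison 3. Except for these fits, the cause was not tested.

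With 1 array left out, counts in the same order ran from 567 to 874, 131 to 343, 285 to 626, 673 to 906, 1056 to 1500 and 644 to 926, the basal signature from 40 to 85, the shared one from 33 to 57, and lists from 7 to 10, 7 to 11, 8 to 12 and 8 to 10. Comparison 2 gave 137 and 131 without remaining basal replicate 1 or 2 and 146 and 139 without Gata6+Itga6+ replicate 1 or 3. Comparison 3 gave 373 and 285 without Gata6+Itga6+ replicate 2 or 3 and 325 and 304 without Gata6+Itga6− replicate 1 or 3. The basal signature was 42 and 40 without remaining basal replicate 1 or 2.

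With the replicate number as a replicate block the counts were 801, 204, 516, 886, 1388 and 886, and with the array row 767, 209, 520, 876, 1372 and 865; both gave signatures of 61 and 47 and lists of 8, 10, 11 and 8. Residuals of arrays sharing either number correlated above 0.1 in 5 of 18 pairs for each (median 0.0089 by replicate number and 0.047 by array row, highest 0.279). Each array row held an array of every population, always in the order Gata6+Itga6+, remaining basal, CD34+ and Gata6+Itga6−. Position within a row therefore cannot be told apart from population in any comparison, and no block removes it. Arrays not sharing a number were not given as a reference, so it stays open whether either number pairs the samples.

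Of 219 called values of named genes under 5694 alternatives in all, 5381 kept direction and call, 303 lost the call and 10 reversed. The brightest probe set alone ended 56 calls and reversed 9 values: Ltbp2 to 0.12 and Ttk to −0.021 for Gata6+Itga6+ against CD34+ cells, Marveld2 to −0.0072 and Ttk to −0.22 against remaining basal cells, Prdm1 to −0.29 and Ttk to 0.15 for Gata6+Itga6− against Gata6+Itga6+ cells, and Lama3 to 0.34, Lgr5 to −0.20 and Ltbp2 to −0.58 for CD34+ against remaining basal cells. The brighter probe sets reversed Lama3 to 0.36 there. The cause was not tested. Signal near background limits these values: 46.5% to 50.2% of probe sets lay under an intensity of 4.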

Other observations

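The symbol family scan was chosen after called Skint genes had been noticed, and the genes named in this part were chosen after their values were seen.

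Besides genes named earlier, the 73 genes higher in both Gata6+Itga6+ and CD34+ cells than in remaining basal cells included Cgnl1, a junction protein related to cingulin (log2 levels 5.82 and 6.08 against 2.07), the ectonucleotidase Nt5e (4.85 and 6.44 against 1.82) and the adhesion receptor Adgrl3 (5.81 and 5.003 against 2.19), each under the level of silent genes in remaining basal cells. The growth factor Ptn (log2 changes 3.59 and 4.63, SE 0.30) and Ndrg2 (3.07 and 4.16, SE 0.31) were others. The small leucine-rich proteoglycan Aspn was at 4.52 in Gata6+Itga6+ and 6.49 in CD34+ cells, against 1.95 in remaining basal and 1.42 in Gata6+Itga6− cells. Aspn was an exception in this, since most of the 73 genes had a higher mean in Gata6+Itga6− than in remaining basal cells. In Gata6+Itga6− cells Cgnl1 was at 6.07, Nt5e at 3.25, Adgrl3 at 6.07, Ptn at 6.25 and Ndrg2 at 7.98. Ptn and Ndrg2 stood at 4.10 and 3.40 in remaining basal cells.

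Of 10 measured Skint genes, immunoglobulin-like genes of skin and thymus, 5 were higher in Gata6+Itga6− than in Gata6+Itga6+ cells. They were Skint2 and Skint8, at 4.09 and 4.65 against 1.89 and 2.45, which lie under the level of silent genes, Skint9 (log2 change 2.17, SE 0.29), Skint10 (1.94) and Skint4 (1.67), while Skint3 (0.31), Skint5 (−1.12), Skint6 (−0.58), Skint7 (−0.43) and Skint11 (−0.03) were not called. Of the latter, all but Skint3 lay under the level of silent genes in Gata6+Itga6− cells. Among 557 families of genes sharing the letters of their symbol, tested in 4 comparisons and 2 directions (4456 tests, one-sided hypergeometric), this gave an adjusted p of 0.0002191. It decides nothing about a random draw of genes, because the scan was prompted by these genes and takes the members of a family as independent. The count was 5 higher and 0 lower also after quantile normalization, centring and the brightness covariate. Members of the family are similar in sequence and may share probe signal, so 5 genes are not 5 independent measurements. A rise of these 5 Skint genes as a program of Gata6+Itga6− cells is a hypothesis that the scan neither favours nor excludes.

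The scan passed 8 tests, each taking members as independent. The others were Skint higher in Gata6+Itga6+ than in CD34+ cells (5 of 10, adjusted p = 0.003979), Igfbp lower (4 of 7, 0.01107), Col lower (7 of 43, 0.03278) and Mcm higher (4 of 10, 0.04571) in the same comparison, Mcm lower in Gata6+Itga6− than in Gata6+Itga6+ cells (4 of 10, 0.03278), and Dsg and Reep lower in CD34+ than in remaining basal cells (3 of 6 each, 0.04991).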
